A study of Mus musculus with 10 samples.

How the data were processed

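Gene expression was measured by RNA-seq in 10 libraries of mouse macrophages, 5 labelled WT and 5 labelled KO for Jaml, each after LPS at 100 ng/ml for 8 h and ATP at 5 mM for 30 min, per the labels. The authors deposited a table of whole-number counts per gene and library, per the file headers. The same deposited table gives FPKM, which for 8180 genes with at least 200 counts in every library equalled the count divided by a gene length and by the library total, with a largest relative spread of 4.5e-06 over the WT libraries. FPKM added no measurement and was not tested. Per the submitters' processing notes, CASAVA 1.8 and TopHat2 2.0.6 were used, and the genome builds mm10 and GRCm39 are both named without a role. The gene counter, annotation, strand setting and filters are not given in the sources used here. Of 52073 gene identifiers shared with an annotation of the older build GRCm38, 1430 had the same position, so coordinates are given as the table lists them and exon positions were not looked up. Without a stated strand setting, overlapping and antisense genes cannot be separated, and reads of near-identical paralogs could have been split or lost.

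Columns were joined to samples by name. The 5 WT columns match the labels. The 5 remaining columns are headed SI, which no label spells out, and were taken as KO by elimination, since the series holds no other group. Their numbers name the libraries, and no label ties such a column to a single KO sample. They were used for counts only, so 5 FPKM columns were not used. The table holds 56980 genes, 27622 of them with a count, and 1542 without a symbol. Where a symbol stood on several identifiers (145 symbols) it was kept by the identifier with the highest count. Libraries held 19319512 to 22766319 counts. A floor of 3 counts corresponded to 0.132 to 0.155 CPM and covers counting error only. No libraries were duplicates: the chi-square per gene was 9.87 to 19.54 within genotypes and 41.06 to 59.59 between them.

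Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3, KO minus WT, with Benjamini-Hochberg adjustment over the 14436 genes kept, which held 99.87% of counts. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is the estimate divided by the square root of its F statistic. CPM values are normalised by the TMM factors. The biological coefficient of variation was 12.8% (11.5% in WT, 14.3% in KO). TMM factors averaged 0.961 in WT and 1.04 in KO (exact permutation test, p = 0.00794, Benjamini-Hochberg adjusted 0.0397 over 5 library measures). The mitochondrial share was 1.40% in WT and 1.54% in KO (exact p = 0.0476, adjusted 0.0793), and the 10 most abundant genes held 12.0% and 11.5% of counts (exact p = 0.0397, adjusted 0.0793). The number of genes detected had an exact p of 0.294 (adjusted 0.368).

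Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 31 lists with at least 3 tested genes. Each list was tested again with an estimated correlation and with fry. The design, the 34 lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Jaml and Lyz2; the 12 genes with the largest fold in each direction among those called, not overlapping between genotypes and with a mean log2 CPM of at least 1; every inflammasome gene at that level; up to 4 members with the smallest p of each other list that passed or held a called gene; and the 2 most abundant members of lists of other cells. Predicted genes without a full name were passed over. It named 163 genes, some of which are not reported here; others are said to be chosen after their values were seen.

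The procedure was tested on simulated data of the same size, KO against WT, over 14258 genes. In these data 50 genes were changed at each fold. The procedure recovered 20% of genes changed 1.25-fold, 58% at 1.5-fold, 86% at 2-fold and 94% at 4-fold, and called 7 of 14039 unchanged genes. The real comparison called 4200 genes, and the Benjamini-Hochberg cutoff depends on the share of changed genes. These recovery rates thus need not hold for the real data. Of 31 simulated lists, the 1 that was shifted was called, with either correlation. Simulated genes were drawn independently of each other, whereas the estimated correlation in the real interferon list was 0.735. The simulation therefore cannot vouch for the list calls made with the preset correlation.

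Alternatives were DESeq2 size factors, library totals without a composition factor, no filter, a filter of 50 counts in 5 libraries, the replicate number as a block (for KO the number in the column name, by assumption), each library left out in turn, robust edgeR, the DESeq2 1.42.0 Wald test and limma-voom. Fits without KO 1 and KO 2, without KO 1 and KO 3 and without genes at 2 levels were added after the data were seen. Group counts were set against 100 splits of the libraries, the real one included. A list of 33 liver transcripts was written after some of them were seen in the data; 13 were tested and none is in the other lists.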

Results

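The data were RNA-seq gene counts from mouse macrophages of 2 genotypes. Per the series labels, the cells came from mice with the junctional adhesion molecule-like gene Jaml intact (WT) or removed in macrophages (KO). Cells of both genotypes had received lipopolysaccharide (LPS, a bacterial ligand of the receptor TLR4) at 100 ng/ml for 8 h and then ATP at 5 mM for 30 min, a sequence that primes and then triggers the NLRP3 inflammasome. There were 10 libraries, 5 WT and 5 KO, and untreated cells were not analysed here. The libraries held 19319512 to 22766319 counts each, 20506200 ± 759039 in WT and 20670600 ± 1314730 in KO (mean ± SD, n = 5 each). A difference in depth did not pass (exact permutation test, two-sided, p = 0.817; the smallest p this design allows is 0.00794). The titles call the second group a macrophage knockout and the genotype tag calls it a knockdown. In the deposited table only the 5 WT columns carry a name that matches the labels. The other 5 columns are headed SI, which the labels do not explain, and were taken as KO because the series has no other group, so every direction below rests on that assignment.

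The targeted gene could not check the labels. Jaml (ENSMUSG00000048534, chromosome 9, 44990481 to 45019832) had 2 counts in WT 1, 2 counts in KO 4 and 0 in the other 8 libraries. All 10 values lay under a floor of 3 counts per library, which corresponds to 0.132 to 0.155 CPM (counts scaled by library size and composition; the floor by size alone), and this floor covers counting error only. Jaml RNA was therefore not detectable at this depth in either genotype, and no fold is given. Lyz2, the macrophage lysozyme gene whose locus often carries Cre in myeloid deletions, was among the most abundant transcripts. Its level was 18210 ± 521 CPM in WT and 17531 ± 722 CPM in KO (mean ± SD, n = 5 each), with an edgeR adjusted p of 0.289. The labels name no Cre line.

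The comparison asked how macrophages of the 2 genotypes differed after the same LPS and ATP treatment. KO macrophages had less RNA from interferon-stimulated genes, inflammatory mediators and most chemokines, and more RNA from enzymes of cholesterol synthesis. With an estimated correlation between genes the list calls held for inflammatory mediators and cholesterol synthesis and were lost for interferon-stimulated genes (camera adjusted p = 0.143) and chemokines (adjusted p = 0.127). Nos2, the inducible nitric oxide synthase, went from 2050 ± 46.4 CPM in WT to 361 ± 44.5 CPM in KO, 5.67-fold lower (mean ± SD, n = 5 each). Among genes that rose, Mmp9, a gelatinase, went from 41.2 ± 2.74 to 139 ± 15.3 CPM, 3.38-fold higher. Of 14436 genes tested, 4200 differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 2036 higher and 2164 lower in KO. Most differences were small, with a median absolute log2 fold change of 0.35 among the genes called. At least 2-fold changes were found for 426 genes, 148 higher and 278 lower. The 5 KO values lay wholly above or below the 5 WT values for 3362 of the tested genes, against the 0.79% that chance gives. The genotypes also separated on the first principal component, which held 39.1% of the variance. With library totals in place of the TMM scaling, the median log2 fold change of all genes moved from 0.01 to 0.12 and the calls became 4231 higher and 1361 lower, so fold changes are given relative to the TMM scaling. The count of at least 2-fold changes was 271 with a stricter filter on low counts and 672 (156 higher, 516 lower) without KO 1 and KO 3, a setting chosen after these libraries were seen to stand apart. Nothing in the labels says that the libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

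Among the largest decreases with fully separated groups, on the log2 scale, Ifit1bl1 fell by 3.82 ± 0.15, Ifi208 by 3.25 ± 0.16, Iigp1 by 2.98 ± 0.17 and Ifi206 by 2.57 ± 0.17 (estimate ± SE, as for all log2 values below). Il27, a cytokine subunit of activated myeloid cells, went from 25.0 ± 2.61 to 2.86 ± 0.845 CPM. Cxcl10, a chemokine that attracts T cells, went from 174 ± 15.7 to 22.4 ± 5.12 CPM, 7.76-fold lower. The serotonin transporter gene Slc6a4 fell by 2.94 ± 0.23, the transcription factor gene Lhx2 by 2.70 ± 0.20, the lipase gene Lipg by 2.67 ± 0.27, the chloride channel gene Clic5 by 2.66 ± 0.13 and the serpin gene Serpina3f by 2.50 ± 0.21. Ifit1bl1, Ifi208, Ifi206 and Serpina3f belong to families of near copies, whose reads the authors' counting could have split, so their single-gene values are uncertain. 

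The largest increases with fully separated groups were of mixed kind. The log2 fold change was 2.37 ± 0.14 for Serpine2, an inhibitor of serine proteases, 2.02 ± 0.08 for the glutamate transporter gene Slc1a2 and 2.00 ± 0.11 for Astn2. Hp, which encodes the haemoglobin-binding protein haptoglobin, went from 378 ± 79.2 to 1290 ± 199 CPM, and Pf4, a CXC chemokine, from 25.2 ± 2.09 to 85.5 ± 5.21 CPM (mean ± SD, n = 5 each). U90926 rose by 1.75 ± 0.07, Tmem119, known as a microglial marker, by 1.74 ± 0.08, and Draxin, an axon guidance gene, by 1.73 ± 0.16. Rab11fip4, Dok7 and Clmn rose by 1.73 ± 0.16, 1.66 ± 0.17 and 1.64 ± 0.21.

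Inflammasome and pyroptosis genes changed in both directions. Of 23 tested, 10 fell, 2 rose and 11 did not pass the test. Nlrp3, the sensor of the inflammasome that bears its name (ENSMUSG00000032691, chromosome 11, 59432394 to 59457782), went from 129 ± 17.7 CPM in WT to 76.5 ± 6.02 CPM in KO, 1.69-fold lower. Casp1, the protease of the complex (ENSMUSG00000025888, chromosome 9, 5298508 to 5307290), was 1.63-fold lower and Gsdmd, the pore-forming gasdermin it cleaves, was 1.51-fold lower. Il18, a cytokine cleaved by caspase-1, showed the largest fold in the list, from 11.8 ± 1.35 to 3.59 ± 0.834 CPM. Casp4, a sensor of LPS inside the cell, fell by 0.93 ± 0.07 on the log2 scale, Mefv, which encodes pyrin, by 0.78 ± 0.06, Casp8 by 0.43 ± 0.05, Il1a by 0.43 ± 0.06, Brcc3 by 0.37 ± 0.06 and the DNA sensor gene Aim2 by 0.35 ± 0.12. Pycard, the adaptor that joins sensor and caspase, moved the other way, from 58.8 ± 5.16 to 92.7 ± 4.37 CPM, 1.57-fold higher. Il1b went from 67.2 ± 8.19 to 80.6 ± 7.53 CPM (edgeR adjusted p = 0.0421).

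Among the inflammasome genes that did not pass the test, the log2 fold change was -0.08 ± 0.17 for Nlrp1a, -0.06 ± 0.06 for Nlrc4, 0.00 ± 0.05 for Naip2, -0.12 ± 0.06 for Naip5 and 0.06 ± 0.16 for Gsdme. It was 0.19 ± 0.18 for P2rx7, the ATP-gated channel upstream of NLRP3, -0.13 ± 0.05 for Panx1, -0.25 ± 0.09 for Ninj1 and 0.45 ± 0.27 for Txnip. Nek7, a binding partner of NLRP3, had 0.58 ± 0.34, with values of 89.4 and 84.8 CPM in KO 2 and KO 3 and 25.8 to 31.0 CPM in the other KO libraries. Nek7 is among the genes that took 2 distinct levels within a genotype, described below, so its values may reflect counting. The list as a whole lay lower in KO (camera adjusted p = 0.00175; adjusted p = 0.0726 with an estimated correlation), and 12 members fell and 2 rose when adjusted over the list alone. The calls of Il1b and Aim2 were not firm: Il1b lost its call without WT 1, WT 2, WT 3, WT 4, KO 1, KO 4 or KO 5 (adjusted p up to 0.0946), and Aim2 without any single library except WT 3 and KO 4 (up to 0.107) and with library totals (0.136), and without a low-count filter both lost theirs (0.0572 and 0.0879). Ninj1 passed with the DESeq2 Wald test (adjusted p = 0.0338), with limma-voom (0.0457), without KO 1 or KO 4 (0.0132 and 0.041) and in the fits added after the data were seen (0.0344 to 0.0485). Panx1 passed without WT 4 (0.0299) and Naip2 with library totals (0.0344).

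**Figure D1:**
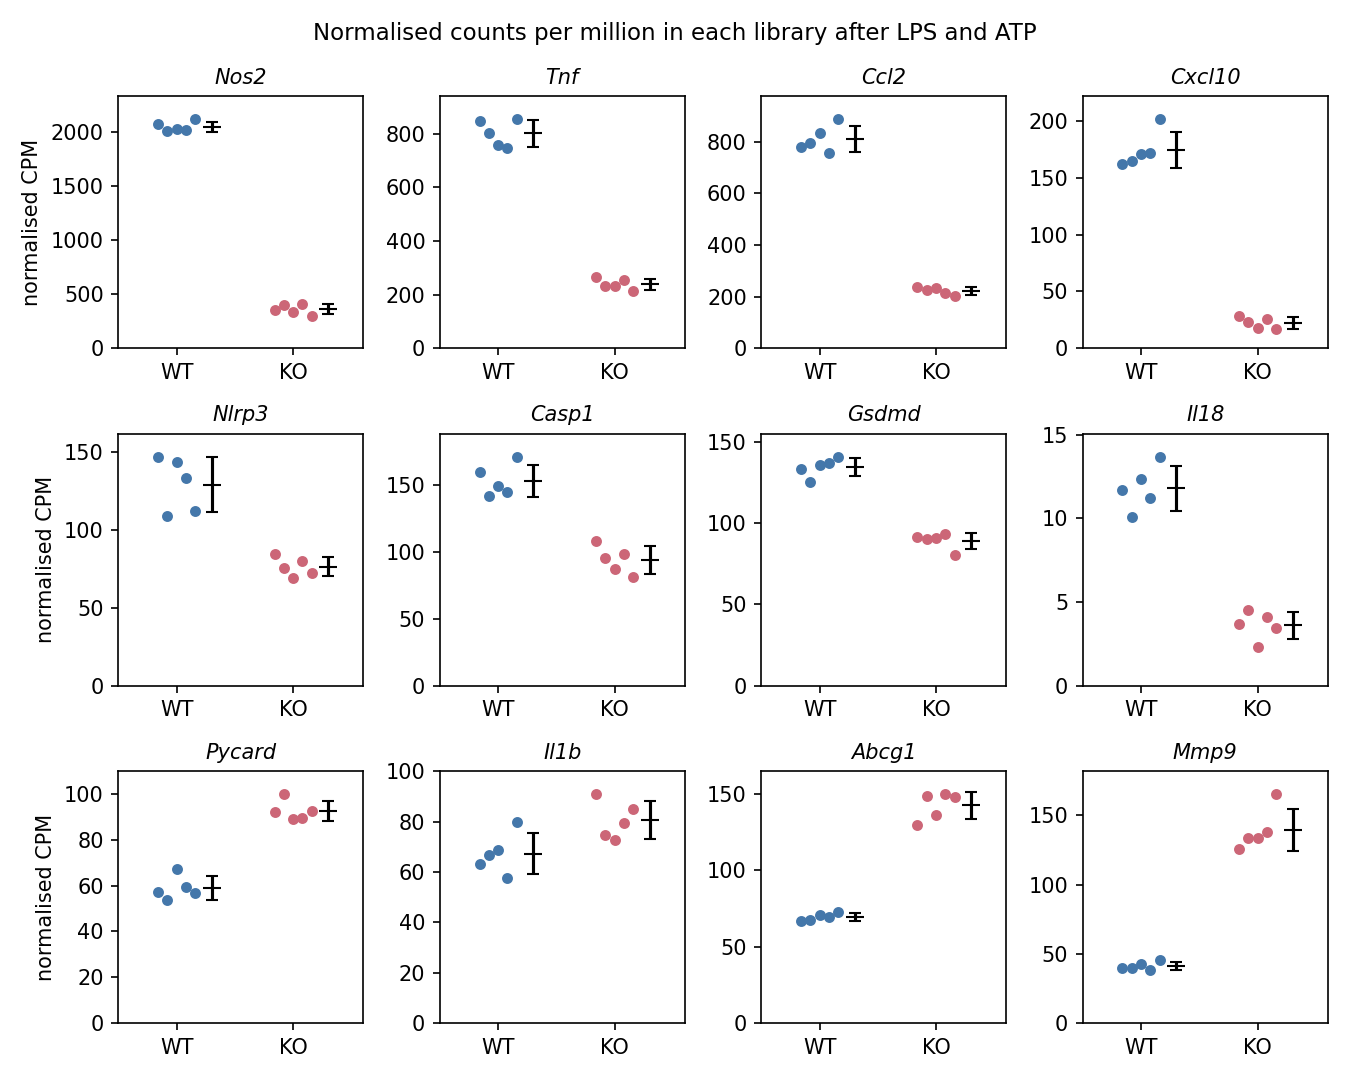
Normalised CPM (linear axes from 0) of 12 genes in the 5 WT (blue) and 5 KO (red) libraries; each point is a library, and the black mark and bar beside the points give the mean and SD. Nos2, Tnf, Ccl2, Cxcl10, Nlrp3, Casp1, Gsdmd and Il18 lie lower in all 5 KO libraries than in any WT library, Pycard, Abcg1 and Mmp9 lie higher, and the Il1b values of the groups overlap.

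Interferon-stimulated genes fell together. Of 47 tested, 45 were lower in KO, none was higher, and the median log2 fold change was -1.15. Rsad2, the antiviral protein viperin, went from 1564 ± 91.0 to 352 ± 62.1 CPM, 4.44-fold lower, and its neighbour Cmpk2 fell by 2.34 ± 0.15 on the log2 scale. Ifi205 fell by 1.91 ± 0.11, and the immunity-related GTPase gene Iigp1 went from 53.6 ± 5.35 to 6.78 ± 2.01 CPM. The list lay lower in KO by camera with its preset correlation (adjusted p = 1.4e-30). Its members rise and fall together within a genotype (correlation 0.735), and the call was lost with an estimated correlation (adjusted p = 0.143). With library totals 45 members were still lower, with a median of -1.03.

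NF-kB targets and inflammatory mediators were mostly lower in KO. Of 36 tested, 30 fell, 1 rose and 5 did not pass. Tnf went from 802 ± 50 to 239 ± 21 CPM, 3.35-fold lower, and Ptgs2, the inducible cyclooxygenase, was 2.39-fold lower. Nos2 and Il27, given above, had the other smallest p-values. The member that rose was Lcn2, a siderophore-binding lipocalin, at 0.69 ± 0.05 on the log2 scale, named after its value was seen. The list lay lower by camera (adjusted p = 1.01e-16), also with an estimated correlation (adjusted p = 0.0232).

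Chemokine genes were mostly lower, 15 of 21 against 4 higher, and at least 2-fold changes were found for 8 that fell and 1 that rose. Ccl2, a monocyte attractant, went from 811 ± 51.8 to 222 ± 15.1 CPM, 3.65-fold lower, and Ccl7 fell by 2.07 ± 0.14 on the log2 scale beside Cxcl10. Pf4, Ccl9, Cxcl3 and Cxcl14 rose; Ccl9, Cxcl3 and Cxcl14 were named after their values were seen, at log2 fold changes of 0.54 ± 0.05, 0.47 ± 0.06 and 0.53 ± 0.17. The list lay lower by camera (adjusted p = 2.98e-06; adjusted p = 0.127 with an estimated correlation).

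Genes of TLR4 and purinergic signalling shifted by less. Of 26 tested, 13 fell and 2 rose. The adenosine receptor gene Adora2a fell by 0.83 ± 0.05 on the log2 scale, the adaptor genes Myd88 and Ticam2 by 0.57 ± 0.04 and 0.48 ± 0.04, and Entpd1, an enzyme that degrades extracellular ATP, by 0.51 ± 0.04. The list lay lower by camera (adjusted p = 0.000751; adjusted p = 0.0726 with an estimated correlation). With library totals its counts were 9 lower and 4 higher.

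Enzymes of cholesterol synthesis rose by small amounts. Of 24 genes tested, 17 rose and 1 fell, with a median log2 fold change of 0.34. Dhcr7, which acts at the end of the pathway, rose by 0.72 ± 0.06 on the log2 scale. Insig1, a brake on the pathway, rose by 0.42 ± 0.03 and Cyp51 by 0.38 ± 0.04. The list lay higher by camera (adjusted p = 1.03e-07), also with an estimated correlation (adjusted p = 0.00829), and 18 members rose and 1 fell when adjusted over the list alone. Without KO 1 and KO 2, a setting chosen after the data were seen, 12 members rose and 1 fell.

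Genes of lipid uptake, storage and efflux moved both ways, 11 higher and 10 lower of 32 tested, and the list did not pass (camera adjusted p = 0.735). Abcg1, a cholesterol efflux transporter, went from 69.3 ± 2.53 to 142 ± 8.92 CPM, 2.06-fold higher. Pparg, a lipid-responsive nuclear receptor, rose from 5.38 ± 0.155 to 12.6 ± 1.36 CPM and the lipoprotein lipase gene Lpl from 441 ± 28.8 to 809 ± 49.7 CPM. The scavenger receptor gene Msr1 fell from 372 ± 19.4 to 223 ± 7.24 CPM.

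**Figure D2:**
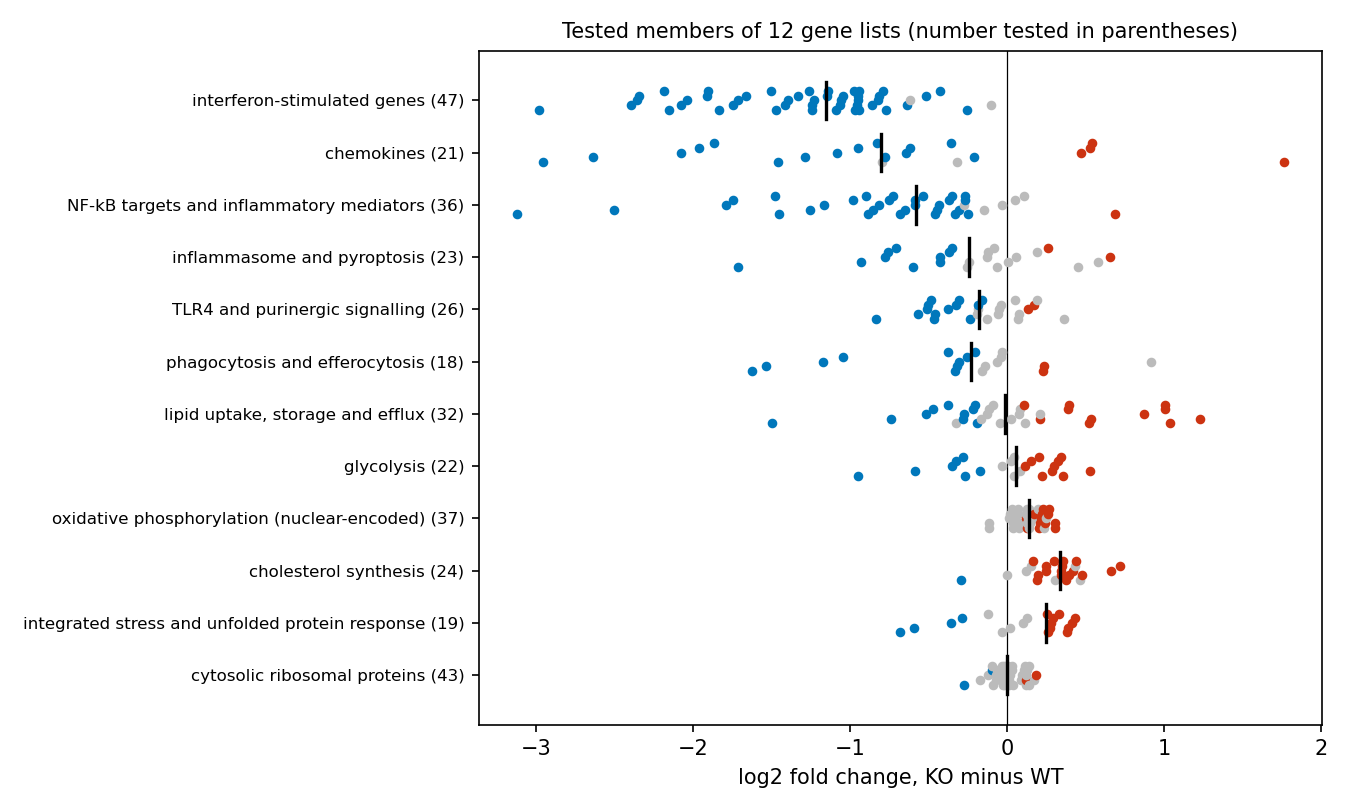
Log2 fold change (KO minus WT, 5 libraries each) of each tested member of 12 gene lists; red and blue points are members called higher and lower at an adjusted p under 0.05, grey points did not pass, and black bars are list medians. The interferon-stimulated genes lie furthest to the left (median -1.15) and the cholesterol synthesis genes to the right (median 0.34), while the ribosomal protein genes lie around 0.

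Metabolic lists moved by smaller amounts. Of 37 nuclear genes of oxidative phosphorylation 13 rose and none fell, among them Cox7a2 at 0.27 ± 0.04, Ndufb9 at 0.26 ± 0.05, Uqcrq at 0.24 ± 0.05 and Ndufb3 at 0.22 ± 0.05 on the log2 scale. That list lay higher by camera (adjusted p = 0.000243; adjusted p = 0.0726 with an estimated correlation), and with library totals 27 members rose. Of 15 mitochondrially encoded transcripts 4 rose, namely mt-Rnr1 by 0.52 ± 0.08, mt-Cytb by 0.30 ± 0.05, mt-Nd3 by 0.53 ± 0.10 and mt-Nd1 by 0.23 ± 0.08, and with library totals 10 rose. The camera call of that list (adjusted p = 0.0218) was lost with an estimated correlation (adjusted p = 0.606) and without WT 3 (adjusted p = 0.0968). Its member mt-Nd4l, which was not called, was at 0.05 CPM in WT 3 and is among the genes at 2 levels described below. mt-Nd1 lost its call without WT 1, WT 2, WT 3, WT 4, KO 1, KO 3 or KO 5 (adjusted p up to 0.0921) and without a low-count filter (0.0544).

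Of 22 glycolysis genes 10 were higher and 7 lower (camera adjusted p = 0.349), and 13 higher and 3 lower with library totals. The hexokinase genes Hk3 and Hk2 fell by 0.95 ± 0.05 and 0.27 ± 0.04, while Aldoc and the lactate transporter gene Slc16a3 rose by 0.53 ± 0.06 and 0.28 ± 0.04. Of 43 cytosolic ribosomal protein genes 2 rose, Rpl38 by 0.18 ± 0.05 and Rpl3 by 0.12 ± 0.04, and 2 fell, among them Rps3 by 0.10 ± 0.03 (camera adjusted p = 0.757). With library totals 13 ribosomal protein genes were higher and 1 lower, and Rps3 turned to 0.02 with no call. Rps3 lost its call without any single library except KO 2 and KO 5 (adjusted p up to 0.111) and Rpl3 without KO 2 or KO 5 (up to 0.0694). Rps3 also lost it without a low-count filter (0.166) and with robust edgeR (0.0526).

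Surface and phagocytic genes were more often lower. Of 18 phagocytosis genes 10 fell and 2 rose, including Fcgr1, a high-affinity IgG receptor, from 182 ± 10.7 to 59.1 ± 7.64 CPM. The efferocytosis receptor gene Axl fell by 1.17 ± 0.06 on the log2 scale, Fcgr4 by 1.04 ± 0.06 and Anxa1 by 0.37 ± 0.04 (list camera adjusted p = 0.000584; adjusted p = 0.145 with an estimated correlation). Of 27 adhesion genes 12 fell and 4 rose. Vcam1 fell by 1.51 ± 0.09 and Icam1 by 0.73 ± 0.04, while the integrin gene Itgax rose from 129 ± 7.53 to 265 ± 13.5 CPM (list camera adjusted p = 0.0213; adjusted p = 0.0726 with an estimated correlation).

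Of 15 alternative activation genes 5 fell and none rose. Msr1 is given above, Mrc1 fell by 0.36 ± 0.05, Maf by 0.35 ± 0.05 and Arg1 by 0.57 ± 0.11 (camera adjusted p = 0.0283; adjusted p = 0.279 with an estimated correlation), and the list lost its call without KO 3 (adjusted p = 0.0676). Of 11 genes in the list of antigen presentation and MHC class II 4 fell. The class II genes H2-Aa and H2-Eb1 fell by 0.36 ± 0.05 and 0.44 ± 0.13. Their transactivator gene Ciita fell by 1.03 ± 0.18 and Cd86, an antigen presentation gene outside class II, by 0.81 ± 0.06. The list, called MHC class II below, had a camera adjusted p of 0.0283, and of 0.145 with an estimated correlation. H2-Eb1 lost its call without WT 2, WT 5, KO 2 or KO 4 (adjusted p up to 0.0599) with library totals (0.0592) and without a low-count filter (0.05).

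Macrophage identity genes were mixed, 4 of 18 higher and 9 lower (camera adjusted p = 0.0703, and 0.0401 without WT 2 or without KO 2). Besides Fcgr1, the complement genes C1qb and C1qc fell by 0.76 ± 0.04 and 0.61 ± 0.05. Of 11 large peritoneal macrophage markers 2 fell, Timd4 by 1.53 ± 0.28 and F10 by 0.12 ± 0.04; Prg4 and Cxcl13 had 0.26 ± 0.13 and -0.80 ± 0.39 (camera adjusted p = 0.283). F10 lost its call with library totals (log2 fold change -0.01), without a low-count filter (adjusted p = 0.135) and without WT 3, WT 4, WT 5, KO 1, KO 3 or KO 4 (up to 0.0969). Prg4 passed without KO 1 (adjusted p = 0.017) and with library totals (0.0316). Of 10 small peritoneal or monocyte-derived markers Vcan fell, by 1.03 ± 0.07, while Clec4a2, Fn1 and Ly6c2 had 0.28 ± 0.11, -0.21 ± 0.09 and 0.36 ± 0.19 (camera adjusted p = 0.394). Fn1 passed without KO 3 (adjusted p = 0.00886) and Clec4a2 without WT 4 or KO 4 (0.0394 and 0.0167) and with library totals (0.0179), and Ly6c2 passed without KO 1 and KO 2 (0.0462), a setting chosen after the data were seen.

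Stress and signalling lists held changes in both directions. Of 19 genes of the integrated stress and unfolded protein responses 10 rose and 4 fell. The chaperone genes Calr, Pdia4 and Dnajc3 rose by 0.41 ± 0.04, 0.43 ± 0.04 and 0.25 ± 0.03, and Sesn2 fell by 0.35 ± 0.05 (camera adjusted p = 0.0283; adjusted p = 0.445 with an estimated correlation; 0.0719 without KO 1 and 0.11 with library totals). Immediate early genes counted 3 higher and 7 lower of 26 (camera adjusted p = 0.221), and their median moved from -0.08 to 0.04 with library totals. Junb, Dusp1 and Maff fell by 0.54 ± 0.04, 0.65 ± 0.06 and 0.42 ± 0.05, and Egr1 rose by 0.76 ± 0.10. Heat shock genes counted 3 higher and 5 lower of 13 (camera adjusted p = 0.572), and 4 higher and 1 lower with library totals. Hspa1a fell by 1.33 ± 0.11 and Hspa8 by 0.21 ± 0.04, the latter without a call under library totals, and Hspe1 and Hsph1 rose by 0.26 ± 0.04 and 0.21 ± 0.04.

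NRF2 and oxidative stress genes counted 3 higher and 5 lower of 18 (camera adjusted p = 0.681), and 7 higher and 4 lower with library totals. Nfe2l2, which encodes NRF2, fell by 0.49 ± 0.04, Slc7a11 by 0.29 ± 0.05 and Hmox1 by 0.20 ± 0.04, while Gpx4 rose by 0.24 ± 0.03. Among 7 NADPH oxidase genes Ncf1 fell by 0.31 ± 0.03, and Cyba and Cybb rose by 0.18 ± 0.03 and 0.17 ± 0.04. That list had a camera adjusted p of 0.757. Lysosome and autophagy genes counted 8 higher and 5 lower of 24 (camera adjusted p = 0.545), and 12 higher and 3 lower with library totals, with Gusb, Map1lc3b and Atg5 up by 0.26 ± 0.04, 0.25 ± 0.04 and 0.21 ± 0.04 while Lamp2 fell by 0.21 ± 0.03. Matrix proteases and inhibitors counted 5 higher and 5 lower of 18 (camera adjusted p = 0.757). Besides Mmp9, Mmp2 rose from 145 ± 18.2 to 320.1 ± 29.7 CPM, and Adam8 and Plaur fell by 0.88 ± 0.06 and 0.49 ± 0.04.

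Cell cycle genes counted 3 higher and 7 lower of 26 (camera adjusted p = 0.178, and 0.037 without KO 3), and 5 higher and 1 lower with library totals. Bub1b, E2f1 and Mcm2 rose by 0.69 ± 0.07, 0.46 ± 0.04 and 0.47 ± 0.08, and Ccna2 fell by 0.39 ± 0.09. KO 1 and KO 3 stood apart from the other KO libraries on the second principal component (17.7% of the variance). Without both, 12 cell cycle genes fell and 3 rose and the list passed (camera adjusted p = 0.00531), a setting chosen after the data were seen. In that setting the lists for alternative activation, MHC class II, endothelial markers, mitochondrial transcripts and the unfolded protein response lost their calls (camera adjusted p = 0.101, 0.0679, 0.0981, 0.0858 and 0.139).

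Markers of other cells did not move alike. Mast cell and basophil markers fell, 4 of 6 tested, with Hdc from 8.90 ± 0.747 to 4.24 ± 0.579 CPM and Cma1, Tpsb2 and Cpa3 lower too, at log2 fold changes of -1.31 ± 0.18, -1.05 ± 0.18 and -1.58 ± 0.41 (camera adjusted p = 0.00318; adjusted p = 0.0726 with an estimated correlation). Among 13 fibroblast and mesothelial markers 4 fell and 3 rose (camera adjusted p = 0.0966, and 0.0329 without KO 3). The collagen genes Col1a1 and Col1a2 rose by 0.37 ± 0.05 and 0.32 ± 0.06, whereas Pdgfra, Upk3b and Lrrn4 fell by 1.01 ± 0.08, 2.69 ± 0.26 and 2.50 ± 0.31. Msln, a mesothelial marker named after its values were seen, was at 8.99 and 11.4 CPM in KO 1 and KO 3, at 0.3 to 1.08 CPM in KO 2, KO 4 and KO 5 and at 5.03 to 9.74 CPM in WT. Krt19 (2.3 and 3.18 CPM against 0.2 to 0.26 CPM) and Igfbp5 (2.67 and 4.39 CPM against 0.05 to 0.3 CPM) divided the KO libraries in the same way. Pdgfra, Pdgfrb, Upk3b and Lrrn4 did not. These genes were compared in this way after their values were seen. Of 3 endothelial markers tested, Kdr and Flt1 fell by 1.45 ± 0.08 and 1.15 ± 0.27 and Cdh5 had -0.03 ± 0.18. The list had a camera adjusted p of 0.0444, and of 0.188 with an estimated correlation, 0.0865 without WT 3 and 0.0688 without KO 3. Its untested members Tek, Tie1, Cldn5, Egfl7 and Ptprb, named after their values were seen, were at 0 to 0.56 CPM in all libraries. The list therefore does not show a change in endothelial content.

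Neutrophil markers counted 3 higher of 6, none lower (camera adjusted p = 0.062, and 0.04 without KO 2). Among markers of this list that were not tested, S100a9, Ly6g, Mpo and Cxcr2 were at 0 to 0.15 CPM in all 10 libraries. These were chosen after their values were seen. The list therefore does not show a change in neutrophil content. Besides Mmp9, S100a8 rose from 14.6 ± 1.33 to 21.5 ± 1.48 CPM and Camp from 2.25 ± 0.204 to 3.27 ± 0.574 CPM. Mmp8 had 0.09 ± 0.07 and Csf3r -0.14 ± 0.05, and Csf3r passed without WT 2 or KO 4 (adjusted p = 0.0489 and 0.0418) and Mmp8 with library totals (0.0275). The dendritic cell list (camera adjusted p = 0.105) held a call for Ccl22, which fell by 1.29 ± 0.18; Fscn1, Ccr7 and Zbtb46 had -0.44 ± 0.18, -0.45 ± 0.29 and -0.28 ± 0.29, and Fscn1 passed without KO 4 (adjusted p = 0.0347). Too few lymphocyte and erythroid markers were tested for a list test. The immunoglobulin gene Ighm went from 1.90 ± 0.724 to 0.502 ± 0.26 CPM and the receptor gene Il7r, also expressed by activated myeloid cells, from 167 ± 7.81 to 101.4 ± 2.48 CPM, while Lck had -0.17 ± 0.16. No erythroid marker reached the count filter, and those named here were chosen after their values were seen. Hbb-bt was at 0.41 and 0.52 CPM in KO 1 and KO 2 and at 0 in the other 8 libraries, Hbb-bs at 0.51 and 0.39 CPM there against 0 to 0.16 CPM, and Hba-a1 at 1.57 and 1.12 CPM against 0 to 0.7 CPM. Alb, the serum albumin gene of hepatocytes, was at 91.3 and 100.7 CPM in KO 1 and KO 2 and at 2.46 to 15.7 CPM in the other 8 libraries; it was chosen after its values were seen. Of the genes called at least 2-fold higher in KO, 5 were liver transcripts whose highest values were in KO 1 and KO 2, namely Serpina1b, Serpina3k, Fga, Fgg and Hpx, also chosen after their values were seen. Hp, another hepatocyte transcript, lay higher in each of the 5 KO libraries, at 1077 to 1543 CPM, than in any WT library.

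In all, 31 of the 34 gene lists held enough genes for a list test, and camera called 11 lower and 4 higher in KO. The lists that passed with an estimated correlation were the NF-kB targets and cholesterol synthesis. Of 100 splits of the libraries, the 21 that exchanged 1 library per side, which leaves most of the genotype contrast in place, called 8 to 18 lists, and the 78 that exchanged 2 called 0 to 8. By the fry test, whose directional p asks whether a list moves on balance in a single direction and whose mixed p asks whether its members change in either direction, neither against other genes, 23 lists passed the directional test. For lipid uptake, storage and efflux the median was -0.01, whereas the mean was 0.07 and camera gave an upward direction. With library totals the counts were 15 higher and 8 lower for these lipid genes, 7 and 8 for macrophage identity, 8 and 5 for matrix proteases, 12 and 2 for the unfolded protein response and 5 and 7 for immediate early genes.

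When adjusted over the list alone, 46 interferon-stimulated genes fell, 30 NF-kB targets fell and 1 rose, 15 chemokines fell and 4 rose, and 14 TLR4 and purinergic genes fell and 2 rose. In the same way 16 genes of oxidative phosphorylation rose, and 10 phagocytosis genes fell and 3 rose. In the lists of alternative activation and of antigen presentation and MHC class II 7 and 6 genes fell. Adhesion genes had 12 lower and 4 higher, mast cell markers 4 lower, endothelial markers 2 lower, the unfolded protein response 10 higher and 4 lower and mitochondrial transcripts 4 higher. Among lists that did not pass, the counts adjusted over the list alone were 12 higher and 11 lower for lipid genes, 11 and 7 for glycolysis, 4 and 7 for immediate early genes, 4 and 9 for macrophage identity, 3 and 7 for cell cycle and 4 and 6 for heat shock. They were 3 higher and 5 lower for NRF2 genes, 3 and 3 for NADPH oxidase, 8 and 6 for lysosome genes, 5 and 5 for matrix proteases, 3 and 4 for fibroblast and mesothelial markers, 3 and 1 for neutrophil markers and 1 and 1 for ribosomal proteins. Large peritoneal, small peritoneal, dendritic, B cell and T and NK cell markers each had 1 lower.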

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

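The tests of scaling and of exposure below were chosen after the results were seen; the splits and the test of stromal markers were planned before. Chance alone sets apart about 1 in 20 groups of 5 libraries by the gap used here, which is 16 of the 326 groups examined, and 23 values stood apart, so chance alone accounts for a large share of such values. Jaml was at 0.0987 CPM in WT 1 and 0.0982 CPM in KO 4 against 0 in the others of each genotype, which is 2 counts in each. Among the most changed genes, WT 5 was highest for Ifit1bl1 (61.1 CPM, others 53.3 to 54.5), Cxcl10 (201 CPM, others 162 to 171) and Serpina3f (4.33 CPM, others 3.21 to 3.5), and KO 5 was highest for Tmem119 (19.2 CPM, others 15.7 to 16.6). Among inflammasome genes, KO 5 was lowest for Gsdmd (80 CPM, others 90.2 to 93) and Panx1 (33.7 CPM, others 35.9 to 36.7) and highest for P2rx7 (91.1 CPM, others 50.8 to 59.5), and WT 1 was highest for Gsdme (4.79 CPM, others 2.92 to 3.38).

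Among surface and identity genes, KO 3 was lowest for Msr1 (211 CPM, others 224 to 229) and highest for Fn1 (677 CPM, others 517 to 529). KO 1 was lowest for Itgax (242 CPM, others 266 to 275) and Mmp2 (268 CPM, others 327 to 343) and highest for Junb (139 CPM, others 127 to 130). KO 5 was highest for H2-Eb1 (25.5 CPM, others 15.3 to 17.5) and KO 4 for Lck (3.04 CPM, others 1.84 to 2.12). In WT, library 3 was highest for C1qc (119 CPM, others 108 to 110) and E2f1 (43 CPM, others 39.7 to 40.6), and library 5 for Sesn2 (37.4 CPM, others 33.9 to 34.3) and Nfe2l2 (395 CPM, others 362 to 369). The lowest WT values were Bub1b in WT 4 (14.5 CPM, others 17.4 to 17.6) and Ncf1 in WT 2 (766 CPM, others 809 to 826).

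Of 100 splits of the libraries into 5 and 5, 1 gave 4200 or more changed genes, namely the real one, and the highest other split gave 2. For changes of at least 2-fold 1 split gave 426 or more, again the real one, and the highest other gave 1. No other split thus reached either count. Every other split mixes the genotypes, so their difference adds to the spread within each side and keeps calls low. These splits therefore show that the libraries divide by group, and cannot tell genotype from another difference between the groups. For gene lists 2 of the 100 splits called 15 or more: the real one and another that called 18. That share makes chance a rare source of this count but does not exclude it. The split with 18 exchanged 1 library per side, as did 21 splits with 8 to 18 lists, so it held most of the genotype contrast, and the 78 splits that exchanged 2 per side called at most 8.

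The decrease of interferon-stimulated genes was weighed against technical causes. With library totals the list median was still -1.03. Changing from TMM to library totals shifts all genes alike, and their median moved only from 0.01 to 0.12. The list was therefore bound to stay low. The choice between these scalings does not account for the decrease, and no other scaling was tested here. Stromal RNA that differs between libraries could not be judged by the test used. With the mean of 13 fibroblast and mesothelial markers in the model the median was -1.14 and 44 of 47 genes were still called lower. That mean joins markers that rose with markers that fell. It also ran largely with genotype, at 3.9 to 4.28 log2 CPM in WT and 2.63 to 3.9 in KO. WT 5 and KO 3 had the same mean, 3.9, while their interferon-stimulated genes averaged 8.46 and 6.94 log2 CPM. A weaker exposure of the KO cultures to LPS and ATP may be a source too, because 30 of 36 NF-kB targets were lower, and without untreated libraries it cannot be told apart from genotype. An effect of genotype stays open as well and is untested apart from exposure.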

How the results depend on the processing

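The fits without KO 1 and KO 2, without KO 1 and KO 3 and without genes at 2 levels were chosen after the data were seen. The count of changed genes stayed between 3541 and 5592 over all alternatives, and no gene called at first was called with the opposite sign in another fit. With library totals 5592 genes were called, 75.7% of them higher against 48.5%, and 3397 of the 4200 were still called, while DESeq2 kept 3980 and limma-voom 4134. At least 2-fold changes numbered 271 with the stricter filter, which tests fewer genes, 672 without KO 1 and KO 3 (the cause was not tested) and 541 with DESeq2. Gene lists called numbered 2 with an estimated correlation and 23 with fry, which does not compare a list with other genes. Rps3 turned from -0.098 to 0.018 with library totals, the scaling that raised the median of all genes.

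With an estimated correlation calls were lost for inflammasome, TLR4 and purinergic, oxidative phosphorylation, adhesion and mast cell genes (camera adjusted p = 0.0726 each), chemokines (0.127), interferon-stimulated genes (0.143), MHC class II and phagocytosis (0.145 each), endothelial markers (0.188), alternative activation (0.279), the unfolded protein response (0.445) and mitochondrial transcripts (0.606). The estimated correlation was 0.735 for interferon-stimulated genes and 0.767 for mitochondrial transcripts. For adhesion and mast cell genes it was -0.007 and -0.001, under the preset 0.01. Correlation between members is thus argued against as the cause for these 2 lists. For inflammasome genes the estimate was 0.013, near the preset 0.01, and the call was lost too. A lost call in this setting therefore cannot be put down to correlation alone, and no other cause was tested for any list. With fry, passing was gained by neutrophil markers (adjusted p = 2.93e-06), macrophage identity (0.00183), small peritoneal markers (0.00473), immediate early genes (0.00533), dendritic cell markers (0.00574), matrix proteases (0.00688), fibroblast and mesothelial markers (0.0108), large peritoneal markers (0.0303) and lipid genes (0.0455), and lost by mitochondrial transcripts (0.0749).

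For the following changes of camera calls the cause was not tested. With library totals dendritic cell (adjusted p = 0.0355) and fibroblast and mesothelial markers (0.0164) passed and the unfolded protein response did not (0.11). Without a low-count filter macrophage identity (0.0376) and fibroblast and mesothelial markers (0.0169) passed and endothelial markers did not (0.624). With the stricter filter neutrophil markers passed (0.0495) and adhesion genes did not (0.0846). Without KO 1 and KO 2 neutrophil markers passed (0.0383). Without KO 1 and KO 3 fibroblast and mesothelial markers (0.00305) and cell cycle genes (0.00531) passed, and MHC class II (0.0679), mitochondrial transcripts (0.0858), endothelial markers (0.0981), alternative activation (0.101) and the unfolded protein response (0.139) did not.

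Leaving out each library in turn gave 3765 to 4085 changed genes, 415 to 477 at least 2-fold, 13 to 18 lists, a difference in library totals of -360000 to 487000 counts (exact permutation p 0.492 to 0.921) and a difference in mean Jaml CPM of -0.0197 to 0.0196. Camera adjusted p ranged from 0.0148 to 0.0676 (alternative activation, highest without KO 3), 0.0401 to 0.114 (macrophage identity, lowest without WT 2 and without KO 2), 0.04 to 0.0849 (neutrophil markers, lowest without KO 2), 0.0329 to 0.191 (fibroblast and mesothelial markers, lowest without KO 3), 0.0263 to 0.0865 (endothelial markers, above the threshold without WT 3 or KO 3), 0.037 to 0.333 (cell cycle, lowest without KO 3), 0.0133 to 0.0719 (unfolded protein response, highest without KO 1) and 0.000929 to 0.0968 (mitochondrial transcripts, highest without WT 3). Named genes that lost a call were Aim2, Il1b, H2-Eb1, F10, mt-Nd1, Rpl3 and Rps3. Among the other genes named, Camp lost its call without KO 1 and KO 3 (adjusted p = 0.0775), Rpl38 without KO 1 and KO 2 (0.0574) and Hspa8 with library totals (0.0705).

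The KO columns match the labels by group, not by sample, so a paired fit needs the assumption that the numbers in their names are the replicate numbers. Under it the numbers do not pair the samples: same-numbered libraries correlated at 0.09, -0.04, -0.11, -0.01 and 0.18, and a WT library matched its own number best only for 1 and 5. With the replicate block 3780 genes were called, 426 at least 2-fold and 14 lists, and endothelial markers (adjusted p = 0.0799), F10 (0.0805), Rpl3 (0.0529) and Rps3 (0.115) lost their calls. Jaml, at 4 counts, was given as a difference of means only, with no value for the filters, the block, robust edgeR, DESeq2 or limma-voom, and depth limits any statement on it to the floor of 3 counts.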

Other observations

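The tests of a shared state, of neighbouring genes and of an acute-phase response below were chosen after the results were seen; those of a fixed counted part and of a single liver profile were planned before the values they measure. Genes at least 2-fold lower in KO lay in clusters on the genome, and all genes in this paragraph were chosen after their values were seen. Of 430 windows of 5 Mb with enough tested genes, 10 held more such genes than a hypergeometric test allows. On chromosome 1 between 170 and 175 Mb, where the DNA-sensing Ifi200 family lies, 17 of 73 tested genes fell at least 2-fold (adjusted p = 1.22e-11), among them Ifi209, Mndal, Ifi204 and Ifi211. Between 85 and 90 Mb of the same chromosome 11 of 54 did (adjusted p = 1.1e-06), among them the nuclear body genes Sp140 and Sp110. On chromosome 19 between 30 and 35 Mb 7 of 29 did (adjusted p = 0.000142), namely Ch25h and members of the Ifit family. On chromosome 7 between 105 and 110 Mb 8 of 46 did (adjusted p = 0.000254), all of the Gvin family of large interferon-inducible GTPases and its pseudogenes, and on chromosome 3 between 15 and 20 Mb the signal-regulatory genes Sirpb1a, Sirpb1b and Sirpb1c were among 4 of 11 (adjusted p = 0.00343). Neighbouring family members share sequence and regulation and are not independent, and only decreases were examined.

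Within 5 Mb of Jaml 29 of 75 tested genes were called, 17 higher and 12 lower, which is 38.7% against 29% elsewhere (Fisher's exact test, two-sided, p = 0.0743).

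Some genes took 2 distinct levels within a genotype: 78 of 7503 examined in WT and 72 in KO, 35 of them in both. Of the 115 genes at 2 levels in either genotype, 5 are in a gene list. These are mt-Nd4l and Gpx1 in WT, Rac1 and Nek7 in KO and Egr2 in both. The mitochondrial transcript mt-Nd4l, named after its values were seen, was at 0.05 CPM in WT 3 and at 134 to 163.5 CPM in the other libraries. In the fit without genes at 2 levels the list of mitochondrial transcripts was still called. Lrrc8d stood at 275.1 CPM in WT 5, 271.9 CPM in KO 2 and 274.4 CPM in KO 4 and at 19.1 to 30.0 CPM in the other libraries. A state shared by the cells of a library is argued against, because the commonest of 15 divisions of the WT libraries held 13 genes, and so are reads moved to a neighbouring gene for most, since 4 genes had such a neighbour. A fixed part of the gene counted in some libraries and not in others may be a cause but cannot be told apart here, since 67.9% of KO values lay near a WT level, between the bounds of that test. No biological explanation other than a shared state was tested.

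Liver transcripts were raised in KO 1 and KO 2: of 13 tested in a list written after some were seen, 10 were highest in those libraries. For each of these 10, WT 2 was the highest WT library (Alb at 15.7 CPM against 2.46 to 4.18 CPM), 8 of the 13 were called between genotypes, 5 of them at least 2-fold higher with their highest values in KO 1 and KO 2, and the erythroid transcript Hbb-bt was detected in KO 1 and KO 2 alone (0.41 and 0.52 CPM). RNA from liver cells may be a source. Over the 10 genes with an excess over the other KO libraries in both, the log2 ratio of the excess in KO 1 to that in KO 2 had an SD of 0.22. Any source that raised these genes alike in both libraries would give such a ratio, so it cannot tell such sources apart. Of the 4 tested markers that are not acute-phase genes, 3 were also highest there, Alb among them. Because Alb and some other members were seen before the list was written, this count cannot decide on an acute-phase response of the macrophages. Contact between samples or tissue carried into the preparation was not tested.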
